A study of Arabidopsis thaliana with 18 samples.

How the data were processed

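Gene expression was measured by RNA sequencing of total RNA from whole seedlings, 3 libraries for each of 6 groups (wild type or ecap-2 after 0, 1 or 3 h on JA). Each deposited table lists one library's gene values in FPKM, per the file headers. FPKM are fragments scaled to transcript length and to the number of mapped fragments. The submitters' processing notes name TopHat2, Cufflinks and the TAIR10 genome, and versions were not given in the sources used here. Groups follow the sample records, which state genotype and hours of treatment and mark both 0 h groups as untreated. The titles differ, with wild type 0 h libraries called controls and the ecap-2 ones JA treatment for 0 h. Of the listed genes, 22122 matched the TAIR10.1 gene table used for names and coordinates.

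Genes with an FPKM of at least 1 in at least 3 libraries were tested, 17835 genes or 80.3% of those listed. Values were taken as log2(FPKM + 1). A linear model with 6 group means was fitted to all 18 libraries with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with empirical Bayes moderation (trend and robust settings, 12 residual degrees of freedom, median prior degrees of freedom 4.56). P-values are two-sided and Benjamini-Hochberg adjusted within each of 11 comparisons at 0.05. The comparisons were JA against 0 h at 1 and 3 h and 3 h against 1 h in wild type, JA against 0 h at 1 and 3 h in ecap-2, ecap-2 against wild type at each time and averaged over times, and the difference of the JA response between the genotypes at 1 and 3 h. Relative depth was estimated from 2731 genes with a mean FPKM under 0.15 as the most common ratio of their values to those of wild type 3 h replicate 2, within 0.6 on the log2 scale. It is approximate.

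The groups, comparisons, 21 gene lists, first alternatives and the rule for naming genes were set before the data were examined. The lists hold 272 genes, of which 256 were in the tables and 228 were tested, and the other 16 were not analysed here. Each list was compared with all other genes by camera with a preset correlation between genes of 0.01, 231 list tests with adjustment within each comparison. The test was then run with a correlation estimated from the data. Of 67 list calls with the preset correlation, 25 held with the estimated one. Fry, which asks whether a list's genes move on balance one way without comparing them with other genes, called 106. A count adjusted over the list alone applies the Benjamini-Hochberg method to that list's genes only.

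AT3G58110 is always named. Candidates are genes past the threshold whose groups' libraries do not overlap and whose higher mean is at least 5 FPKM. Some of their 5 largest rises and 5 falls per comparison are named. From each list come up to 4 members of smallest p-value, or up to 2 of highest mean where none passed. For comparisons of genotypes and of responses, any member of the late anthocyanin, anthocyanin regulator and JAZ lists is open to naming. For comparisons of more than a pair of groups the rule did not say what overlap means. That reading was set after the data were seen. For the average over times, the genotypes' libraries had to lie apart at each of the 3 times. For a difference of responses, the libraries' log2 values less their own genotype's 0 h mean had to lie apart. AT3G58110 was taken as ECAP from general knowledge, since neither the labels nor the gene table use that name.

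Alternatives were a pseudocount of 0.1 or 5, no filter or a mean of at least 5 FPKM, rescaling to a common total, quantile normalization and trimmed mean scaling with a share of 0.3 trimmed. Further ones were plain empirical Bayes, only the libraries compared, replicate number as a block, library weights, a change of at least 2-fold, and leaving out each library in turn. Chosen after the data were seen were a correction of each library for GC content and spliced length (splines with 5 degrees of freedom each), and that correction with the block. So were nuclear genes only, leaving out single libraries for the list tests, and the lists of iron deficiency, heat shock, EARLI1 cluster and organelle genes. The model was tested on simulated data of 17835 genes with 200 changed genes in each of 5 rounds. It recovered 94.4% of genes with a log2 change of 1 in the design of wild type at 3 h, 95% for ecap-2 against wild type at 3 h, 98.6% for the average over times and 84.6% for the difference of responses at 3 h, with 5.92%, 4.15%, 4.62% and 4.38% of calls false. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.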

Results

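RNA was sequenced from whole Arabidopsis seedlings of the Col-0 wild type and of the mutant ecap-2, grown for 6 days and then moved to plates with 50 µM jasmonic acid (JA) for 0, 1 or 3 h. Each of the 6 groups held 3 libraries, 18 in all. The series title names ECAP as a protein that links JAZ repressors to the co-repressor TPR2 and restrains JA-responsive anthocyanin. Its design text sets wild type as the control. The comparisons below therefore ask what JA changed in each genotype, what differed between the genotypes at each time, and whether the response to JA differed between them. Each library had 20136 to 20520 genes above 0 and 1689 to 2073 listed at 0. Total FPKM per library ran from 687996 to 765209 in wild type, from 760383 to 801831 in ecap-2 at 0 and 1 h, and from 853858 to 912834 in ecap-2 at 3 h. The read depth behind each FPKM is unknown. Depth relative to wild type 3 h replicate 2, estimated from genes of low FPKM, ran from 0.737 to 1.27. Levels are means ± SD in FPKM over the 3 libraries of a group (n = 3). Changes are on the log2(FPKM + 1) scale ± SE, which understates the change of genes near 0. A gene list is called where its test against all other genes gave an adjusted p under 0.05. No mock-treated seedlings at 1 or 3 h were analysed here, so transfer to a new plate and time of day changed together with JA. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

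The targeted gene AT3G58110, the locus taken here as ECAP (chromosome 3, 21516635 to 21519862, + strand, 2 exons), was far lower in ecap-2 in every library. In wild type it measured 14.2 ± 1.1 FPKM (SD, n = 9), with a range of 12.3 to 16.1. In ecap-2 it measured 2.59 ± 0.17 FPKM (SD, n = 9), with a range of 2.34 to 2.89, and wild type had 5.5 times the ecap-2 level. At 0 h the libraries held 16.1, 14.4 and 14.8 FPKM in wild type and 2.43, 2.65 and 2.89 in ecap-2. At 1 h they held 14.1, 14.9 and 14.9 in wild type and 2.48, 2.48 and 2.67 in ecap-2. At 3 h they held 12.3, 12.8 and 13.8 in wild type and 2.62, 2.34 and 2.72 in ecap-2. The log2 difference between the genotypes was -2.14 ± 0.07 at 0 h (adjusted p = 8.6e-12), -2.14 ± 0.07 at 1 h (adjusted p = 8.4e-12) and -1.97 ± 0.07 at 3 h (adjusted p = 3.1e-11). On JA the gene measured a log2 change of -0.20 ± 0.07 in wild type at 3 h (adjusted p = 0.04). That call ended with a pseudocount of 0.1 (adjusted p = 0.064). It also ended without wild type 0 h replicate 1 (0.16) or 3 (0.061) or wild type 3 h replicate 1 (0.15) or 2 (0.099), with a range of 0.012 to 0.16 over the alternatives.

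**Figure D1:**
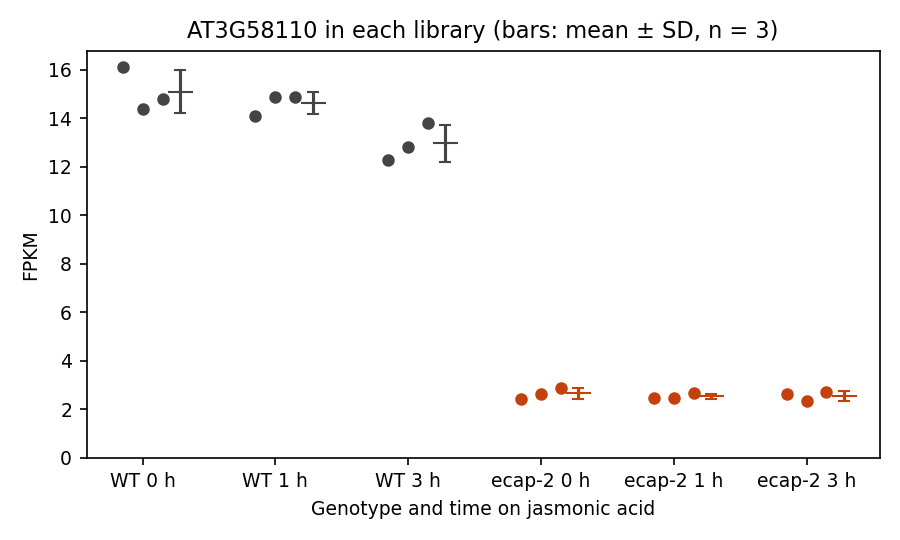
FPKM of AT3G58110 (vertical axis) in each of the 18 libraries (points) by genotype and hours on JA, with each group's mean and SD (bars, n = 3). The wild-type libraries lie between 12.3 and 16.1 FPKM and the ecap-2 libraries between 2.34 and 2.89.

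In wild type at 1 h, genes that make, modify and sense JA rose together. JOX4, an oxygenase that hydroxylates JA, rose from 0.0938 ± 0.025 to 92.4 ± 11 FPKM (log2 change 6.41 ± 0.11, adjusted p = 1.4e-16). The JA-inducible tyrosine aminotransferase gene TAT3 rose from 1.11 ± 0.52 to 129 ± 5.5 FPKM (log2 change 5.98 ± 0.16, adjusted p = 6.6e-14). FAMT, which encodes a farnesoic acid methyltransferase, rose from 0.798 ± 0.45 to 101 ± 14 FPKM (log2 change 5.85 ± 0.20, adjusted p = 3.2e-12). Among the largest falls, the scaffold gene BT2 went from 105 ± 58 to 8.03 ± 5.4 FPKM (log2 change -3.52 ± 0.62, adjusted p = 0.00062). The iron-regulated transcription factor gene BHLH101 fell from 26.5 ± 3.6 to 1.9 ± 0.72 FPKM (log2 change -3.27 ± 0.29, adjusted p = 3.4e-07). Its relative BHLH100 fell from 35.5 ± 11 to 2.99 ± 0.41 FPKM (log2 change -3.15 ± 0.32, adjusted p = 2.3e-06). These 6 genes were picked among those whose groups' libraries did not overlap.

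Of the JA biosynthesis genes, 12 of 13 rose and 1 fell (12 and 1 adjusted over the list alone). Their median log2 change was 2.76 (adjusted p = 2.6e-14, and adjusted p = 0.0081 with an estimated correlation). OPR3, a reductase of the peroxisomal steps, rose from 16.3 ± 1.1 to 198 ± 18 FPKM. Of the JA turnover genes, whose products modify JA or its derivatives, 8 of 9 rose and 0 fell (8 and 0 adjusted over the list alone). As a list they had a median log2 change of 2.91 (adjusted p = 1e-11, and adjusted p = 0.0092 with an estimated correlation). Of the JAZ repressors, which bind and block MYC transcription factors, 9 of 11 rose and 0 fell (9 and 0 adjusted over the list alone). The list's median log2 change was 3.21 (adjusted p = 1.1e-11, and adjusted p = 0.0081 with an estimated correlation). JAZ10 (AT5G13220) rose from 4.55 ± 1.2 to 187 ± 26 FPKM. Of the JA receptor and transcription factor genes, 8 of 11 rose and 0 fell (10 and 0 adjusted over the list alone). The members' median log2 change was 0.58 (adjusted p = 3.1e-05, and adjusted p = 0.017 with an estimated correlation). MYC2, the main activator, rose from 12.6 ± 2.6 to 72.3 ± 6.4 FPKM. Of the co-repressor genes, 1 of 6 rose and 3 fell (1 and 3 adjusted over the list alone). NINJA, the adaptor between JAZ proteins and TOPLESS, rose by 0.96 ± 0.07, while TPR2 had a log2 change of -0.45 ± 0.08 and TPL of -0.28 ± 0.07. Of the JA-induced defence genes, 7 of 10 rose and 1 fell (7 and 1 adjusted over the list alone). Across the list the median was 2.23 (adjusted p = 2.7e-05, and adjusted p = 0.088 with an estimated correlation).

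The early flavonoid genes moved the other way (adjusted p = 0.13 with an estimated correlation). Of the genes of early phenylpropanoid and flavonoid synthesis, 1 of 11 rose and 10 fell (1 and 10 adjusted over the list alone). Over these members the median was -1.21 (adjusted p = 3.7e-08, and adjusted p = 0.13 with an estimated correlation). FLS1, which encodes flavonol synthase, fell from 182 ± 10 to 44.5 ± 1.6 FPKM (adjusted p = 2.1e-09). Of the late anthocyanin genes, 1 of 12 rose and 2 fell (1 and 2 adjusted over the list alone), and the list was not called (median -0.26, adjusted p = 0.42). The glutathione transferase gene TT19 was the member that fell under all alternatives run (log2 change -1.41 ± 0.34). Of the anthocyanin regulators, 4 of 15 rose and 3 fell (4 and 3 adjusted over the list alone). The MYB activator PAP1 rose from 0.819 ± 0.32 to 9.15 ± 3.5 FPKM (log2 change 2.43 ± 0.36, adjusted p = 0.0001).

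Glucosinolate and tryptophan genes rose, the aliphatic list with adjusted p = 0.062 with an estimated correlation. Of the indole glucosinolate genes, 12 of 16 rose and 2 fell (13 and 2 adjusted over the list alone). This list had a median log2 change of 1.31 (adjusted p = 8.4e-11, and adjusted p = 0.023 with an estimated correlation). Of the aliphatic glucosinolate genes, 12 of 12 rose and 0 fell (12 and 0 adjusted over the list alone). They had a median log2 change of 1.21 (adjusted p = 2.6e-09, and adjusted p = 0.062 with an estimated correlation). All 6 tested tryptophan biosynthesis genes rose (6 adjusted over the list alone). With a median of 1.31 this list was called (adjusted p = 1.3e-07, and adjusted p = 0.0084 with an estimated correlation). Of the circadian clock genes, 2 of 13 rose and 7 fell (2 and 7 adjusted over the list alone). The median across members was -0.29 (adjusted p = 0.041, and adjusted p = 0.3 with an estimated correlation). LHY, a gene active at dawn, fell from 230 ± 36 to 88.4 ± 12 FPKM. The clock call ended without wild type 0 h replicate 1 (adjusted p = 0.076) or 2 (0.06) or wild type 1 h replicate 2 (0.055) or 3 (0.056). Leaving out ecap-2 0 h replicate 1 (0.056) or 3 (0.06) ended it too, as did a pseudocount of 5 (0.051) and a correction for GC content and length (0.061).

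The other lists were not called at 1 h. Among touch and early stress genes 4 of 13 rose and 5 fell (5 and 5 adjusted over the list alone), median 0.19. Among salicylic acid genes 1 of 9 rose and 3 fell (1 and 3 adjusted over the list alone), median -0.12. Among auxin response genes 3 of 10 rose and 5 fell (3 and 6 adjusted over the list alone), median -0.45. None of 11 cell cycle genes passed by limma, also adjusted over the list alone (1 at an unadjusted p under 0.05), and CYCB2;1 had a log2 change of 0.10 ± 0.07. Among photosynthesis genes 5 of 17 rose and 1 fell (5 and 1 adjusted over the list alone), median 0.13 (called without wild type 1 h replicate 1, adjusted p = 0.047). Among root markers 1 of 12 rose and 5 fell (1 and 5 adjusted over the list alone), median -0.20. Among seed storage genes 0 of 6 rose and 2 fell (0 and 2 adjusted over the list alone), median -0.84. Of the reference genes, 0 of 5 rose and 2 fell (0 and 2 adjusted over the list alone), and ACT2 fell from 558 ± 25 to 444 ± 24 FPKM. Their median of 0.02 and their test had opposite signs, and the median turned negative after rescaling to a common total. In total 3080 of 17835 tested genes rose and 2970 fell (33.9% of those tested), 1073 of them by at least 2-fold.

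By 3 h in wild type, storage protein and JA synthesis genes stood among the largest rises. The lipoxygenase gene LOX2 rose from 5.6 ± 0.81 to 428 ± 86 FPKM (log2 change 6.01 ± 0.25, adjusted p = 6.7e-11). The storage protein gene VSP2 rose from 0.444 ± 0.15 to 130 ± 29 FPKM (log2 change 6.48 ± 0.60, adjusted p = 1.5e-06), and VSP1 rose from 1.99 ± 0.55 to 99.9 ± 12 FPKM. HSP70 (AT3G12580), a heat shock chaperone gene, fell from 174 ± 27 to 9.2 ± 1.3 FPKM (log2 change -4.10 ± 0.22, adjusted p = 8.7e-10). The light-induced gene ELIP2 fell from 699 ± 10 to 53.6 ± 8.9 FPKM (log2 change -3.70 ± 0.16, adjusted p = 1.8e-11), and LHY fell from 230 ± 36 to 17.2 ± 1.6 FPKM. Lack of overlap was again a condition for these 6 genes.

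Of the JA biosynthesis genes, 12 of 13 rose and 0 fell (12 and 0 adjusted over the list alone). Their median change was 1.69 (adjusted p = 4.6e-11, and adjusted p = 0.012 with an estimated correlation). The JA turnover list was called as well, as 8 of 9 rose and 1 fell (8 and 1 adjusted over the list alone). The median log2 change was 1.94 (adjusted p = 5.4e-08, and adjusted p = 0.033 with an estimated correlation). All 11 tested JAZ genes rose (11 adjusted over the list alone), JAZ1 by 3.24 ± 0.10 and JAZ10 by 4.65 ± 0.16. With a median of 2.49 the JAZ list was called (adjusted p = 2.1e-10, and adjusted p = 0.012 with an estimated correlation). Of the JA receptor and transcription factor genes, 7 of 11 rose and 2 fell (7 and 2 adjusted over the list alone). Their median log2 change was 0.50 (adjusted p = 0.014, and adjusted p = 0.12 with an estimated correlation). Of the JA-induced defence genes, 7 of 10 rose and 1 fell (7 and 2 adjusted over the list alone). As a list they had a median log2 change of 3.06 (adjusted p = 3.8e-05, and adjusted p = 0.11 with an estimated correlation). In the early flavonoid list, 0 of 11 rose and 10 fell (0 and 10 adjusted over the list alone). The list's median log2 change was -1.09 (adjusted p = 1.5e-07, and adjusted p = 0.15 with an estimated correlation). F3H, a flavanone hydroxylase gene, fell from 283 ± 10 to 66.4 ± 13 FPKM (log2 change -2.09 ± 0.16, adjusted p = 2.2e-08).

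Late anthocyanin genes split at 3 h. In this list 6 of 12 rose and 2 fell (7 and 2 adjusted over the list alone). It was not called (median 0.37, adjusted p = 0.14, and adjusted p = 0.042 without wild type 3 h replicate 3). DFR (dihydroflavonol reductase, AT5G42800) rose from 5.71 ± 0.5 to 15.4 ± 4.4 FPKM (log2 change 1.26 ± 0.28, adjusted p = 0.0019). The malonyltransferase gene 5MAT rose from 0.858 ± 0.2 to 3.67 ± 1.1 FPKM, whereas the glucosyltransferase gene UGT78D2 fell from 77.1 ± 16 to 32.8 ± 5.3 FPKM (log2 change -1.20 ± 0.21, adjusted p = 0.00023). Of the anthocyanin regulators, 5 of 15 rose and 2 fell (5 and 2 adjusted over the list alone). PAP1 had a log2 change of 2.25 ± 0.36 and the repressor gene MYBL2 of 1.92 ± 0.32. Of the indole glucosinolate genes, 14 of 16 rose and 1 fell (14 and 1 adjusted over the list alone). The members' median log2 change was 1.62 (adjusted p = 6.2e-11, and adjusted p = 0.032 with an estimated correlation). All 12 tested aliphatic glucosinolate genes rose (12 adjusted over the list alone), with a median of 1.96 (adjusted p = 4.6e-11, and adjusted p = 0.04 with an estimated correlation). MAM1, which encodes a chain-elongation enzyme, rose from 8.41 ± 2.1 to 69.1 ± 4.8 FPKM. All 6 tryptophan genes rose (6 adjusted over the list alone), with a median of 1.45 (adjusted p = 5.1e-07, and adjusted p = 0.012 with an estimated correlation).

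Of the root markers, 1 of 12 rose and 7 fell (1 and 8 adjusted over the list alone). Across the list the median was -0.42 (adjusted p = 0.045, and adjusted p = 0.39 with an estimated correlation). The iron transporter gene IRT1 fell from 59.3 ± 12 to 4.67 ± 2.1 FPKM, and PYK10 rose by 0.91 ± 0.07. The root call ended without wild type 3 h replicate 2 (adjusted p = 0.062), with no filter (0.058) or after a correction for GC content and length (0.12). Photosynthesis genes were not called (adjusted p = 0.052), although 11 of 17 rose and 3 fell (12 and 5 adjusted over the list alone). They were called without wild type 0 h replicate 2 (adjusted p = 0.031) or 3 (0.024) or wild type 1 h replicate 1 (0.024). A pseudocount of 5 (0.044), no filter (0.031), the replicate block (0.044) and the GC and length correction (0.004) also called them. Clock genes went both ways, as 6 of 13 rose and 5 fell (6 and 5 adjusted over the list alone). Their median of 0.22 differed in sign from their mean and test. CCA1 fell by 2.41 on the log2 scale, and PRR5 and PRR7, active later in the day, rose by 2.39 ± 0.12 and 1.72 ± 0.09. The auxin and reference lists also differed in sign between median and test (medians -0.05 and 0.00), and the reference median turned negative under common-total scaling and under quantile normalization. In total 3817 genes rose and 3583 fell (41.5%), 1204 by at least 2-fold. Upward genes were 51.6% of all that passed, and 39.2% (3100 up and 4806 down) after rescaling to a common total.

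Between 1 h and 3 h in wild type, JA turnover and JAZ genes fell and late anthocyanin genes rose as lists, all lost with an estimated correlation (adjusted p = 0.67, 0.67 and 0.72). OPR3 fell from 198 ± 18 to 102 ± 11 FPKM. VSP1 rose from 30 ± 4.2 to 99.9 ± 12 FPKM (log2 change 1.70 ± 0.27, adjusted p = 0.0003), and DFR rose from 4.05 ± 2.1 to 15.4 ± 4.4 FPKM (log2 change 1.75 ± 0.28, adjusted p = 0.00024). Of the JA turnover genes, 2 of 9 rose and 7 fell (2 and 7 adjusted over the list alone). Over these members the median was -0.79 (adjusted p = 0.0017, and adjusted p = 0.67 with an estimated correlation). Of the JAZ genes, 1 of 11 rose and 8 fell (1 and 9 adjusted over the list alone). This list had a median log2 change of -0.44 (adjusted p = 0.022, and adjusted p = 0.67 with an estimated correlation). The JAZ call ended without wild type 1 h replicate 3 (adjusted p = 0.061) or wild type 3 h replicate 1 (0.054), or with a pseudocount of 0.1 (0.099). Of the late anthocyanin genes, 6 of 12 rose and 0 fell (6 and 0 adjusted over the list alone). They had a median log2 change of 0.73 (adjusted p = 0.021, and adjusted p = 0.72 with an estimated correlation). The late anthocyanin call ended without wild type 1 h replicate 3 (adjusted p = 0.061) or wild type 3 h replicate 2 (0.059). Of the aliphatic glucosinolate genes, 7 of 12 rose and 0 fell (8 and 0 adjusted over the list alone). The median across members was 0.50 (adjusted p = 0.00057, and adjusted p = 0.67 with an estimated correlation). JA biosynthesis genes were not called, with 3 of 13 rising and 8 falling (3 and 8 adjusted over the list alone). They were called without wild type 1 h replicate 2 (adjusted p = 0.031) or wild type 3 h replicate 2 (0.046), or with no filter (0.026). In total 2579 genes rose and 2585 fell (29%), 528 by at least 2-fold.

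In ecap-2 at 1 h, JA genes rose together and early flavonoid genes fell (adjusted p = 0.18 with an estimated correlation). JAZ10 rose from 2.99 ± 0.6 to 214 ± 33 FPKM (log2 change 5.75 ± 0.16, adjusted p = 7.6e-14). For JA biosynthesis, 12 of 13 rose and 1 fell (12 and 1 adjusted over the list alone). Their median change was 2.39 (adjusted p = 1.1e-13, and adjusted p = 0.0069 with an estimated correlation). For JA turnover, 8 of 9 rose and 0 fell (8 and 0 adjusted over the list alone). The median log2 change was 3.04 (adjusted p = 1.8e-12, and adjusted p = 0.0075 with an estimated correlation). In the JAZ list, 9 of 11 rose and 0 fell (9 and 0 adjusted over the list alone). Their median log2 change was 3.27 (adjusted p = 1.8e-12, and adjusted p = 0.0069 with an estimated correlation). In the transcription factor list, 8 of 11 rose and 0 fell (8 and 0 adjusted over the list alone). As a list they had a median log2 change of 0.62 (adjusted p = 0.0002, and adjusted p = 0.032 with an estimated correlation). In the defence list, 7 of 10 rose and 0 fell (7 and 1 adjusted over the list alone). The list's median log2 change was 2.14 (adjusted p = 4.8e-06, and adjusted p = 0.07 with an estimated correlation). Early flavonoid genes fell as a list, as 1 of 11 rose and 10 fell (1 and 10 adjusted over the list alone). The members' median log2 change was -0.91 (adjusted p = 1.2e-06, and adjusted p = 0.18 with an estimated correlation). Among indole glucosinolate genes, 12 of 16 rose and 1 fell (12 and 2 adjusted over the list alone). Across the list the median was 1.29 (adjusted p = 1.2e-09, and adjusted p = 0.033 with an estimated correlation). Among aliphatic glucosinolate genes, 11 of 12 rose and 0 fell (11 and 0 adjusted over the list alone). Over these members the median was 0.92 (adjusted p = 2.4e-08, and adjusted p = 0.072 with an estimated correlation). All 6 tryptophan genes rose (6 adjusted over the list alone), and their list was called (adjusted p = 1.3e-07, and adjusted p = 0.0075 with an estimated correlation). Among clock genes, 2 of 13 rose and 7 fell (2 and 8 adjusted over the list alone). This list had a median log2 change of -0.27 (adjusted p = 0.0026, and adjusted p = 0.12 with an estimated correlation). PAP1 rose from 3.67 ± 1 to 29 ± 12 FPKM. In total 2959 genes rose and 3025 fell (33.6%), 1048 by at least 2-fold.

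In ecap-2 at 3 h late anthocyanin genes rose as a list (adjusted p = 0.28 with an estimated correlation). Of these, 10 of 12 rose and 1 fell (10 and 1 adjusted over the list alone). They had a median log2 change of 1.33 (adjusted p = 0.00028, and adjusted p = 0.28 with an estimated correlation). 5MAT rose from 4.75 ± 0.61 to 23.8 ± 3.7 FPKM (adjusted p = 7.5e-07). The glycosyltransferase gene UGT79B1 rose from 4.88 ± 1.1 to 20.4 ± 3.2 FPKM, UGT75C1 from 11.5 ± 2.8 to 44.3 ± 9.7 FPKM and PAP1 from 3.67 ± 1 to 20.1 ± 2.9 FPKM. In the early flavonoid list 2 of 11 rose and 8 fell (2 and 8 adjusted over the list alone). The median across members was -0.56 (adjusted p = 0.013, and adjusted p = 0.59 with an estimated correlation). FLS1 had a log2 change of -2.20 ± 0.13, while F3'H, which encodes the flavonoid hydroxylase of the B ring, rose from 5.91 ± 0.62 to 15.9 ± 3.4 FPKM (log2 change 1.28 ± 0.16, adjusted p = 6.7e-06).

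The JA lists were again called in ecap-2 at 3 h, that of transcription factors with adjusted p = 0.082 with an estimated correlation. For JA biosynthesis, 13 of 13 rose and 0 fell (13 and 0 adjusted over the list alone). Their median change was 1.73 (adjusted p = 2.1e-11, and adjusted p = 0.017 with an estimated correlation). For JA turnover, 8 of 9 rose and 0 fell (8 and 0 adjusted over the list alone). The median log2 change was 2.29 (adjusted p = 5.7e-09, and adjusted p = 0.021 with an estimated correlation). For the JAZ genes, 9 of 11 rose and 0 fell (9 and 0 adjusted over the list alone). Their median log2 change was 2.22 (adjusted p = 5.9e-09, and adjusted p = 0.017 with an estimated correlation). For the transcription factors, 8 of 11 rose and 1 fell (8 and 1 adjusted over the list alone). As a list they had a median log2 change of 0.53 (adjusted p = 0.0059, and adjusted p = 0.082 with an estimated correlation). For defence, 8 of 10 rose and 0 fell (9 and 0 adjusted over the list alone). The list's median log2 change was 3.08 (adjusted p = 3e-07, and adjusted p = 0.041 with an estimated correlation). Among indole glucosinolate genes 13 of 16 rose and 1 fell (13 and 1 adjusted over the list alone). The members' median log2 change was 1.70 (adjusted p = 2.1e-11, and adjusted p = 0.021 with an estimated correlation). All 12 aliphatic genes rose (12 adjusted over the list alone), with a median of 1.67 (adjusted p = 1.5e-10, and adjusted p = 0.041 with an estimated correlation). All 6 tryptophan genes did so too (6 adjusted over the list alone), with a median of 1.52 (adjusted p = 7.9e-07, and adjusted p = 0.017 with an estimated correlation). Among photosynthesis genes 12 of 17 rose and 1 fell (12 and 1 adjusted over the list alone). Across the list the median was 0.65 (adjusted p = 0.00043, and adjusted p = 0.45 with an estimated correlation). In total 4114 genes rose and 3951 fell (45.2%), 1303 by at least 2-fold. Upward genes made up 51% of all that passed, and 25.9% (2495 up and 7120 down) after rescaling to a common total, which moved the median of all genes to -0.168.

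**Figure D2:**
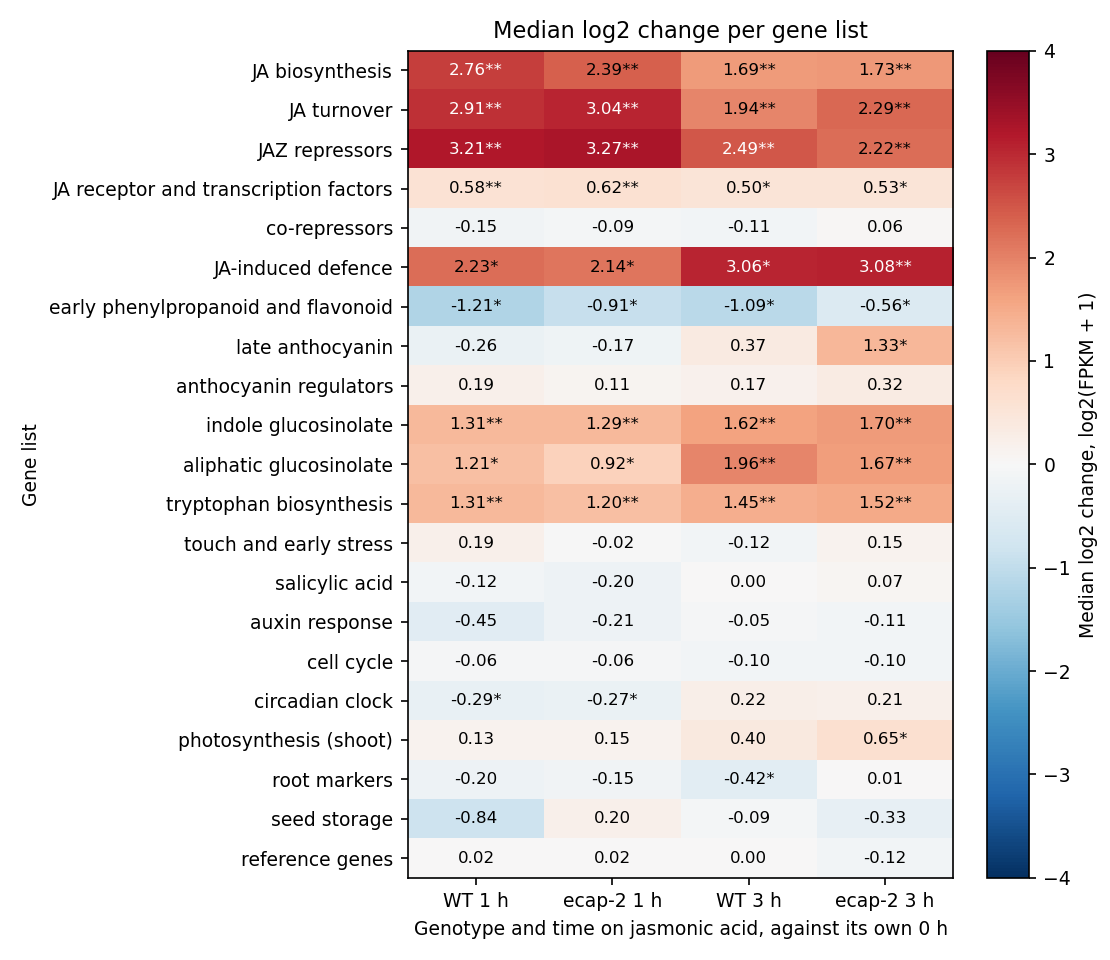
Median log2 change of the tested members of each of 21 gene lists (vertical axis, colour scale) after 1 or 3 h on JA against 0 h in wild type and ecap-2 (horizontal axis, n = 3 per group). A star marks an adjusted p under 0.05 and a pair of stars one that held with an estimated correlation. JA biosynthesis (2.76 in wild type at 1 h) and JAZ repressors (3.21) are among the warmest cells and early flavonoid genes (-1.21) are cold, while the near-zero medians change sign for co-repressors (ecap-2 at 3 h, common total), root markers (ecap-2 at 3 h, common total and quantile) and reference genes (wild type, common total, and at 3 h quantile).

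Across genes the responses of the genotypes were alike. Over the 17835 tested genes, which are not independent replicates, the log2 changes in wild type and ecap-2 correlated with r = 0.899 (Spearman 0.805) at 1 h and r = 0.871 (0.762) at 3 h. The slopes of ecap-2 on wild type were 0.91 and 0.905. At 1 h, 2233 genes rose in both genotypes against 511 expected from independent calls, 2217 fell in both against 503.7, and 9 went opposite ways. At 3 h these numbers were 2819 against 880.5, 2470 against 793.7, and 60. Each genotype's responses at 1 and 3 h share that genotype's 0 h libraries, but the genotypes share none.

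At 0 h, before JA, ecap-2 already differed from wild type in 7880 genes. In comparisons of genotypes, levels run from wild type to ecap-2, and rose and fell mean higher and lower in ecap-2. The late anthocyanin gene DFR rose from 5.71 ± 0.5 to 32.6 ± 9.2 FPKM (log2 difference 2.29 ± 0.28, adjusted p = 1.7e-05). UGT75C1 rose from 2.44 ± 0.23 to 11.5 ± 2.8 FPKM (log2 difference 1.84 ± 0.24, adjusted p = 2.6e-05). TT8, which encodes the bHLH partner of the MYB activators, rose from 0.46 ± 0.15 to 4.28 ± 0.69 FPKM (log2 difference 1.85 ± 0.16, adjusted p = 2.6e-07). AZI1, a lipid transfer protein gene, rose from 53.6 ± 7.3 to 387 ± 19 FPKM (log2 difference 2.84 ± 0.12, adjusted p = 2.4e-10). RGF9, a root meristem growth factor gene, fell from 54.9 ± 15 to 2.67 ± 1.1 FPKM (log2 difference -3.94 ± 0.26, adjusted p = 5.3e-08). The transcript AT1G75945 rose from 0.059 ± 0.1 to 33.9 ± 4.5 FPKM. The plastid gene ATCG00640 was 0 in the 3 ecap-2 libraries (5.12 ± 8.9 FPKM at 1 h, 6.54 ± 11 at 3 h).

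Of the late anthocyanin genes at 0 h, 6 of 12 were higher and 1 lower (6 and 2 adjusted over the list alone), median 0.63. The list was not called (adjusted p = 0.08), and was called without wild type 1 h replicate 3 (adjusted p = 0.038) or with replicate number as a block (0.047). 5MAT rose by 1.63 ± 0.22, UGT79B1 by 1.49 ± 0.21 and LDOX by 1.05 ± 0.27, and BGLU10 had a log2 change of -0.76 ± 0.10. UGT78D2, UGT84A2, 3AT1, 3AT2 and SAT did not pass (0.20, 0.08, 0.00, 0.18 and -0.42). TT19 rose by 1.14 ± 0.34 (adjusted p = 0.014). The TT19 call was lost without wild type 0 h replicate 3 (adjusted p = 0.055, in a range of 0.0025 to 0.055). Of the anthocyanin regulators, 3 of 15 were higher and 1 lower (3 and 1 adjusted over the list alone). PAP1 rose from 0.819 ± 0.32 to 3.67 ± 1 FPKM (log2 difference 1.35 ± 0.36, adjusted p = 0.0079). Its call ended with a pseudocount of 5 (adjusted p = 0.085, in a range of 0.00083 to 0.085). ETC1, a single-repeat MYB gene, fell by 1.03. The early flavonoid list was lower, as 0 of 11 were higher and 7 lower (0 and 7 adjusted over the list alone). Over these members the median was -0.44 (adjusted p = 0.034, and adjusted p = 0.91 with an estimated correlation). That list's call ended without wild type 0 h replicate 1 (adjusted p = 0.053) or ecap-2 0 h replicate 3 (0.097).

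Of the JAZ genes at 0 h, 3 of 11 were higher and 2 lower (3 and 2 adjusted over the list alone), and the median was -0.02. JAZ12 (0.45 ± 0.08) and JAZ11 (0.53 ± 0.09) were higher under every alternative run. The calls of JAZ4 (0.38), JAZ9 (-0.42) and JAZ10 (-0.46) ended under several alternatives. After the GC and length correction JAZ9 had adjusted p = 0.3 and JAZ10 0.51. JAZ10 had 0.094 with a pseudocount of 5 and 0.11 under quantile normalization, and JAZ4 had 0.076 after rescaling to a common total. JAZ10 had adjusted p = 0.12 without wild type 0 h replicate 1, 0.095 without replicate 2, 0.1 without ecap-2 0 h replicate 2 and 0.071 without replicate 3. JAZ9 had 0.11 without wild type 0 h replicate 2 or 3, 0.12 without ecap-2 0 h replicate 1 and 0.061 without replicate 2. JAZ4 had 0.084 without wild type 0 h replicate 3 and 0.11 without ecap-2 0 h replicate 2. JAZ1, JAZ2, JAZ3, JAZ7, JAZ8 and JAZ13 did not pass (-0.01, -0.11, -0.13, -0.30, 0.08 and -0.02). JA biosynthesis genes were not called (adjusted p = 0.05), with 7 of 13 rising and 2 falling (7 and 2 adjusted over the list alone). LOX2 rose from 5.6 ± 0.81 to 24.5 ± 7.8 FPKM (log2 difference 1.91 ± 0.25, adjusted p = 3.6e-05). That list was called with no filter (adjusted p = 0.04), with the block (0.047) and with a pseudocount of 0.1 (0.05, under the threshold before rounding). It was also called without wild type 1 h replicate 3 (adjusted p = 0.038), wild type 3 h replicate 2 (0.045), ecap-2 0 h replicate 1 (0.045) or 2 (0.047), or ecap-2 1 h replicate 1 (0.03), 2 (0.047) or 3 (0.043). The turnover gene CYP94B1 was lower, from 11.5 ± 1.8 to 3.96 ± 0.54 FPKM (log2 difference -1.33 ± 0.10, adjusted p = 8e-08).

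Several aliphatic glucosinolate and cell cycle genes were lower at 0 h, and both list calls were lost with an estimated correlation (adjusted p = 0.91 each). Of the aliphatic genes, 0 of 12 were higher and 7 lower (0 and 7 adjusted over the list alone). This list had a median log2 difference of -0.35 (adjusted p = 0.039, and adjusted p = 0.91 with an estimated correlation). The sulfotransferase gene SOT17 fell from 12.7 ± 1.4 to 7.3 ± 1.1 FPKM. The aliphatic call ended without wild type 0 h replicate 1 (adjusted p = 0.095) or 3 (0.066) or ecap-2 0 h replicate 2 (0.14) or 3 (0.097), or with a pseudocount of 5 (0.066). Of the cell cycle genes, 0 of 11 were higher and 5 lower (0 and 6 adjusted over the list alone). They had a median log2 difference of -0.28 (adjusted p = 0.039, and adjusted p = 0.91 with an estimated correlation). The mitotic cyclin gene CYCB2;2 fell from 3.49 ± 0.39 to 0.877 ± 0.055 FPKM. KNOLLE, a cytokinesis syntaxin gene, fell from 19 ± 1.3 to 12.5 ± 1 FPKM. The cell cycle call ended without wild type 0 h replicate 1 (adjusted p = 0.094) or ecap-2 0 h replicate 3 (0.097). Both calls ended after a correction for GC content and length (0.073 for aliphatic and 0.058 for cell cycle genes). PR1, a salicylic acid marker, was listed at 0 in wild type and measured 2.54 ± 0.44 FPKM in ecap-2. In total 3774 genes were higher and 4106 lower in ecap-2 (44.2%), 629 by at least 2-fold (209 higher and 420 lower). The upward 47.9% became 28.2% (2306 up and 5861 down) under common-total scaling, which moved the median of all genes to -0.108.

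At 1 h several late anthocyanin genes were higher in ecap-2, though their list was not called (adjusted p = 0.1). DFR rose from 4.05 ± 2.1 to 23.9 ± 4.8 FPKM (log2 difference 2.37 ± 0.28, adjusted p = 1.5e-05). TT19 rose from 3.45 ± 2.1 to 15.2 ± 2.8 FPKM (log2 difference 1.99 ± 0.34, adjusted p = 0.00037). UGT75C1 had a log2 difference of 1.93 ± 0.24 (adjusted p = 1.9e-05). TT8 rose from 0.289 ± 0.2 to 3 ± 0.81 FPKM (log2 difference 1.63 ± 0.16, adjusted p = 1.2e-06), and PAP1 rose from 9.15 ± 3.5 to 29 ± 12 FPKM. AT4G12495 and AT1G47130 measured 0 in wild type and 18.1 ± 3.5 and 31.1 ± 16 FPKM in ecap-2. ATCG00300 and AT5G17305 measured 263 ± 400 and 30.2 ± 27 in wild type and 0 in ecap-2 (AT5G17305 10.3 ± 11 at 0 h).

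Of the late anthocyanin genes at 1 h, 6 of 12 were higher and 1 lower (6 and 1 adjusted over the list alone), median 0.68. BGLU10 was the lower one, and UGT78D2, UGT84A2, 3AT1, 3AT2 and SAT did not pass. Without wild type 1 h replicate 1 the list was called (adjusted p = 0.018). The aliphatic glucosinolate list was lower, as 0 of 12 were higher and 6 lower (0 and 7 adjusted over the list alone). The median across members was -0.49 (adjusted p = 0.018, and adjusted p = 0.69 with an estimated correlation). SOT17 fell from 71.9 ± 3 to 45 ± 1.2 FPKM. In the JAZ list, 4 of 11 were higher and 1 lower (4 and 2 adjusted over the list alone). JAZ4 rose by 0.71 ± 0.12, JAZ8 by 0.92 ± 0.17 and JAZ11 by 0.36 ± 0.09. In total 3201 genes were higher and 3912 lower (39.9%), 569 by at least 2-fold. The upward 45% became 28.4% (2147 up and 5407 down) under common-total scaling, which moved the median of all genes to -0.101.

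At 3 h the genotype difference in late anthocyanin genes was called as a list (adjusted p = 0.0037, and adjusted p = 0.79 with an estimated correlation). DFR rose from 15.4 ± 4.4 to 122 ± 13 FPKM (log2 difference 2.94 ± 0.28, adjusted p = 8.2e-07). UGT75C1 rose from 5.35 ± 1.3 to 44.3 ± 9.7 FPKM (log2 difference 2.83 ± 0.24, adjusted p = 2e-07), and TT19 rose from 11.5 ± 3.9 to 79.9 ± 13 FPKM. UGT78D2 rose from 32.8 ± 5.3 to 95.3 ± 17 FPKM (log2 difference 1.51 ± 0.21, adjusted p = 2.1e-05). F3'H, lower in ecap-2 at 0 h, was higher at 3 h, from 5.99 ± 1.8 to 15.9 ± 3.4 FPKM (log2 difference 1.29 ± 0.16, adjusted p = 6e-06). TT8 rose from 0.681 ± 0.18 to 6.11 ± 0.95 FPKM (log2 difference 2.08 ± 0.16, adjusted p = 4e-08), and PAP1 rose from 8.33 ± 4.4 to 20.1 ± 2.9 FPKM. BAM5, a beta-amylase gene, rose from 6.75 ± 2.1 to 129 ± 38 FPKM (log2 difference 4.06 ± 0.28, adjusted p = 5.7e-08). AT1G75945 measured 0 in wild type and 31.4 ± 3.1 FPKM in ecap-2. ATCG00300 and AT5G04238 were listed at 0 in ecap-2.

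In the late anthocyanin list at 3 h, 9 of 12 were higher and 1 lower (9 and 1 adjusted over the list alone). Their median difference was 1.61 (adjusted p = 0.0037, and adjusted p = 0.79 with an estimated correlation). BGLU10 was the member that fell, and UGT84A2 (0.07) and SAT (0.01) did not pass. Of the anthocyanin regulators, 5 of 15 were higher and 1 lower (5 and 1 adjusted over the list alone), and their list was not called. In the JAZ list, 3 of 11 were higher and 1 lower (3 and 1 adjusted over the list alone). JAZ12 rose by 0.54 ± 0.08, and JAZ7 fell from 9.37 ± 1.3 to 2.05 ± 0.85 FPKM (log2 difference -1.80 ± 0.34, adjusted p = 0.00037). JAZ1 stayed at 0.00 (261 ± 13 and 261 ± 12 FPKM) but passed as lower under quantile normalization (adjusted p = 0.029, in a range of 0.029 to 1). The JAZ median of -0.00 changed sign under trimmed mean scaling. JA biosynthesis genes were not called (adjusted p = 0.093), and 6 rose and 1 fell, also adjusted over the list alone. They were called without wild type 3 h replicate 2 (adjusted p = 0.037).

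Of the aliphatic glucosinolate genes at 3 h, 0 of 12 were higher and 7 lower (0 and 7 adjusted over the list alone). The median log2 difference was -0.57 (adjusted p = 0.029, and adjusted p = 0.79 with an estimated correlation). The aliphatic call ended without ecap-2 3 h replicate 3 (adjusted p = 0.059). Of the cell cycle genes, 0 of 11 were higher and 5 lower (0 and 5 adjusted over the list alone). Their median log2 difference was -0.39 (adjusted p = 0.028, and adjusted p = 0.79 with an estimated correlation). The cell cycle call ended without ecap-2 3 h replicate 1 (adjusted p = 0.069). Of the root markers, 9 of 12 were higher and 1 lower (9 and 1 adjusted over the list alone). As a list they had a median log2 difference of 0.60 (adjusted p = 0.022, and adjusted p = 0.79 with an estimated correlation). The root-hair expansin gene EXP18 rose from 16.6 ± 1 to 38.7 ± 5 FPKM (log2 difference 1.17 ± 0.10, adjusted p = 9.3e-08). Of the photosynthesis genes, 11 of 17 were higher and 0 lower (12 and 0 adjusted over the list alone). The list's median log2 difference was 0.30 (adjusted p = 0.0037, and adjusted p = 0.79 with an estimated correlation), a median that turned to -0.09 under quantile normalization. Both organ lists lost their calls after a correction for GC content and length (adjusted p = 0.15 for root and 0.95 for photosynthesis), as did the aliphatic and cell cycle lists (0.067 each). In total 5144 genes were higher and 5108 lower (57.5%), 1136 by at least 2-fold (386 higher and 750 lower). The upward 50.2% became 24.1% (2565 up and 8086 down) under common-total scaling, which moved the median of all genes to -0.197.

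Averaged over the 3 times, the late anthocyanin, aliphatic glucosinolate and cell cycle lists were called, and none with an estimated correlation (adjusted p = 0.83 each). DFR rose by 2.53 ± 0.16 (adjusted p = 4.1e-09) and TT8 by 1.85 ± 0.09, and UGT75C1 (adjusted p = 2.2e-09) and PAP1 (adjusted p = 3.3e-05) rose as well. Of the late anthocyanin genes, 9 of 12 were higher and 1 lower (9 and 1 adjusted over the list alone). The members' median log2 difference was 0.97 (adjusted p = 0.022, and adjusted p = 0.83 with an estimated correlation). Of the aliphatic glucosinolate genes, 0 of 12 were higher and 10 lower (0 and 11 adjusted over the list alone). Across the list the median was -0.43 (adjusted p = 0.022, and adjusted p = 0.83 with an estimated correlation). Of the cell cycle genes, 0 of 11 were higher and 9 lower (0 and 9 adjusted over the list alone). Over these members the median was -0.25 (adjusted p = 0.022, and adjusted p = 0.83 with an estimated correlation). Among the JAZ genes, 4 of 11 were higher and 2 lower (4 and 2 adjusted over the list alone). JAZ12 was at 0.42 ± 0.05 and JAZ7 at -0.97 ± 0.19. Photosynthesis genes were not called (adjusted p = 0.073), with 10 of 17 rising and 1 falling (10 and 1 adjusted over the list alone). They were called without wild type 0 h replicate 2 or 3 or wild type 1 h replicate 2 (adjusted p = 0.045 each) or wild type 1 h replicate 3 (0.049), or with no filter (0.036). Their median of 0.18 turned negative under quantile normalization. RBCS and LHCB1 members are nearly identical in sequence, so values of single members are uncertain.

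In total 6000 genes were higher and 6257 lower (68.7%) averaged over times, 653 by at least 2-fold. The upward 49% became 29% (3625 up and 8866 down) under common-total scaling, which moved the median of all genes to -0.136. Genotype differences at separate times share no libraries. Across the 17835 genes they correlated with r = 0.85 (0 and 1 h), 0.84 (0 and 3 h) and 0.809 (1 and 3 h), and 2312 genes were higher and 2709 lower at all 3 times. They also followed GC content (rank correlation over 17790 genes 0.21 at 0 h, 0.2 at 1 h and 0.32 at 3 h).

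**Figure D3:**
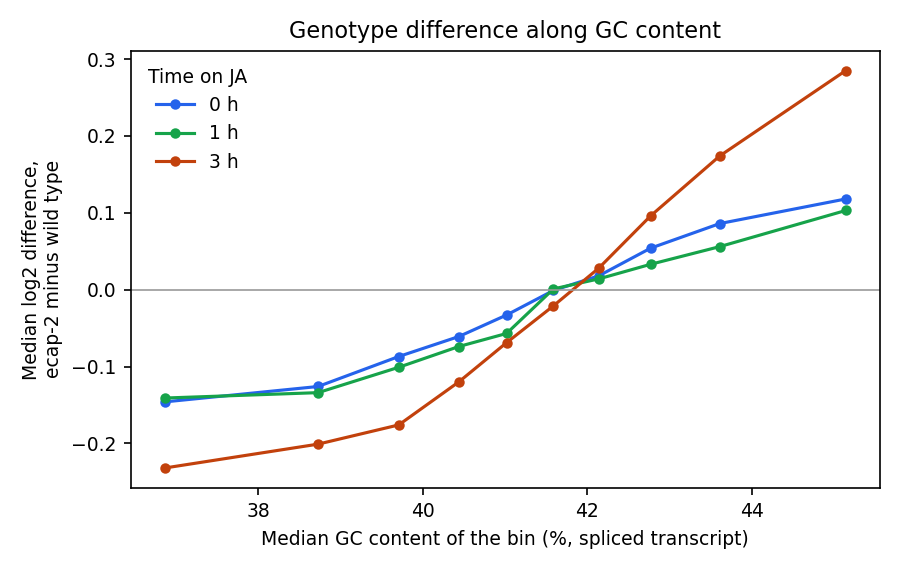
Median log2 difference of ecap-2 against wild type (vertical axis) in 10 groups of genes ordered by GC content of the spliced transcript (horizontal axis, percent) at 0, 1 and 3 h (lines, n = 3 libraries per group). At 3 h the medians run from -0.232 at 36.87% GC to 0.285 at 45.14%.

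The response to JA differed between the genotypes in few genes at 1 h. LTI78, a cold and drought response gene, rose less in ecap-2. It went from 4.98 to 86.5 FPKM in wild type and from 7.57 to 43.7 in ecap-2 (difference of log2 changes -1.48 ± 0.22, adjusted p = 0.011). CYP94B1 had a larger log2 rise in ecap-2, from a lower 0 h level, at 3.96 to 92.5 FPKM against 11.5 to 119 in wild type (0.98 ± 0.15, adjusted p = 0.0082). Its call ended with a pseudocount of 5 (adjusted p = 0.051, the highest over its alternatives). GA20OX5, a gibberellin oxidase gene, went from 0.256 to 3.33 FPKM in wild type and from 0.76 to 18.8 in ecap-2 (1.70 ± 0.21, adjusted p = 0.0022). The GA20OX5 call ended with a pseudocount of 0.1 (adjusted p = 0.3, the highest over its alternatives). None of the 11 JAZ, 12 late anthocyanin and 15 regulator genes passed by limma (1, 0 and 0 passed adjusted over the list alone, and 2, 0 and 0 at an unadjusted p under 0.05). JAZ10 measured 0.65 ± 0.22, DFR 0.08 ± 0.39, TT8 -0.22 ± 0.23 and PAP1 0.21 ± 0.51.

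A test over lists called 3 of 21 at 1 h, and none with an estimated correlation (adjusted p = 0.092 to 0.93). Here changed more upward means a more positive log2 change on JA, which is a smaller one where genes fell. Among JA biosynthesis genes, 0 of 13 changed more upward in ecap-2 and 0 more downward (1 and 4 adjusted over the list alone, and 5 at an unadjusted limma p under 0.05). This list had a median log2 difference of -0.25 (adjusted p = 0.048, and adjusted p = 0.93 with an estimated correlation). Among salicylic acid genes, 1 of 9 changed more upward in ecap-2 and 0 more downward (2 and 0 adjusted over the list alone). They had a median log2 difference of 0.26 (adjusted p = 0.011, and adjusted p = 0.092 with an estimated correlation). Among seed storage genes, 0 of 6 changed more upward in ecap-2 and 0 more downward (0 and 0 adjusted over the list alone, and 0 at an unadjusted limma p under 0.05). The median across members was 1.18 (adjusted p = 0.017, and adjusted p = 0.93 with an estimated correlation). The salicylic acid member that passed was ALD1 (1.21 ± 0.15), which makes an immune signal from lysine. All 3 calls ended with no filter on low values (adjusted p = 0.11, 0.11 and 0.12). The JA biosynthesis and seed storage calls also ended with a pseudocount of 5 (0.1 each), and that of JA biosynthesis with the block (0.063) and after the GC and length correction (0.06). The seed storage call ended without wild type 1 h replicate 3 (adjusted p = 0.066) or ecap-2 0 h replicate 1 (0.068) or 3 (0.23). The JA biosynthesis call ended without wild type 0 h replicate 2 (0.1) or 3 (0.092), wild type 1 h replicate 1 (0.2) or 3 (0.074), or wild type 3 h replicate 1 (0.053) or 3 (0.051). It also ended without ecap-2 0 h replicate 1 (0.065) or 3 (0.12), ecap-2 1 h replicate 2 (0.15) or 3 (0.13), or any ecap-2 3 h replicate (0.057, 0.07 and 0.065). The early flavonoid list, not called here, was called without wild type 1 h replicate 1 (0.04), ecap-2 0 h replicate 1 (0.014) or ecap-2 1 h replicate 2 (0.038). In total 56 genes passed, 30 with a more positive and 26 with a more negative change in ecap-2, against 1394 at an unadjusted p under 0.05. The count was 22 without ecap-2 1 h replicate 2, 32 without ecap-2 0 h replicate 2, 35 without wild type 1 h replicate 2, and 36 without wild type 0 h replicate 2 or wild type 1 h replicate 1. It was 15 with only the libraries compared, 32 with a pseudocount of 0.1, 114 with a pseudocount of 5, 213 with library weights and 107 with the block and the GC and length correction.

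At 3 h the response to JA differed in 432 genes. F3'H fell in wild type, from 11.9 ± 0.59 to 5.99 ± 1.8 FPKM, and rose in ecap-2, from 5.91 ± 0.62 to 15.9 ± 3.4 (difference of log2 changes 2.19 ± 0.23, adjusted p = 0.00075). C4H, which hydroxylates cinnamate, fell less in ecap-2, from 288 to 231 FPKM against 390 to 196 in wild type (0.67 ± 0.11, adjusted p = 0.0081). CYP94B1 again had a larger log2 rise (0.94 ± 0.15) from a lower 0 h level, and it stayed lower in ecap-2 at 3 h, at 63 against 82.9 FPKM (-0.40 ± 0.10). CYP81F3 of indole glucosinolate synthesis rose more in ecap-2 (0.88 ± 0.16). D27, a strigolactone synthesis gene, fell more in ecap-2, from 11.2 to 7.32 FPKM in wild type and from 8.54 to 1.81 in ecap-2 (-1.23 ± 0.19, adjusted p = 0.005). BGLU18, a beta-glucosidase gene, rose less, from 6.59 to 211 in wild type and from 9.54 to 127 (-1.19 ± 0.22, adjusted p = 0.011).

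Of the early phenylpropanoid and flavonoid genes, 5 of 11 changed more upward in ecap-2 and 0 more downward (9 and 0 adjusted over the list alone). Their median difference was 0.67 (adjusted p = 2.3e-08, and adjusted p = 0.5 with an estimated correlation). C4H, CHI and CHIL were among these and fell in wild type. Among late anthocyanin genes, 1 of 12 changed more upward in ecap-2 and 0 more downward (7 and 0 adjusted over the list alone). The median log2 difference was 0.68 (adjusted p = 4.6e-05, and adjusted p = 0.5 with an estimated correlation). The late anthocyanin gene that passed was UGT78D2, which fell in wild type and measured 89.1 and 95.3 FPKM in ecap-2 (adjusted p = 0.033). That call ended without wild type 0 h replicates 1 (adjusted p = 0.065) and 2 (0.068) and wild type 3 h replicates 1 (0.074) and 3 (0.08). It also ended without ecap-2 0 h replicates 2 (0.092) and 3 (0.077) and ecap-2 3 h replicates 1 (0.084) and 2 (0.093), with a range of 0.00045 to 0.093. TT19 (1.59 ± 0.47, adjusted p = 0.09), UGT79B1 (1.06 ± 0.30, adjusted p = 0.067), UGT75C1 (0.99 ± 0.34), DFR (0.64 ± 0.39), PAP1 (-0.06 ± 0.51) and TT8 (0.23 ± 0.23) did not pass. None of the 15 regulators or 11 JAZ genes passed by limma, also adjusted over the list alone (0 and 1 at an unadjusted p under 0.05). JAZ1 measured 0.01 ± 0.14, and the JAZ median of 0.01 turned negative under common-total, quantile and trimmed mean scaling.

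**Figure D4:**
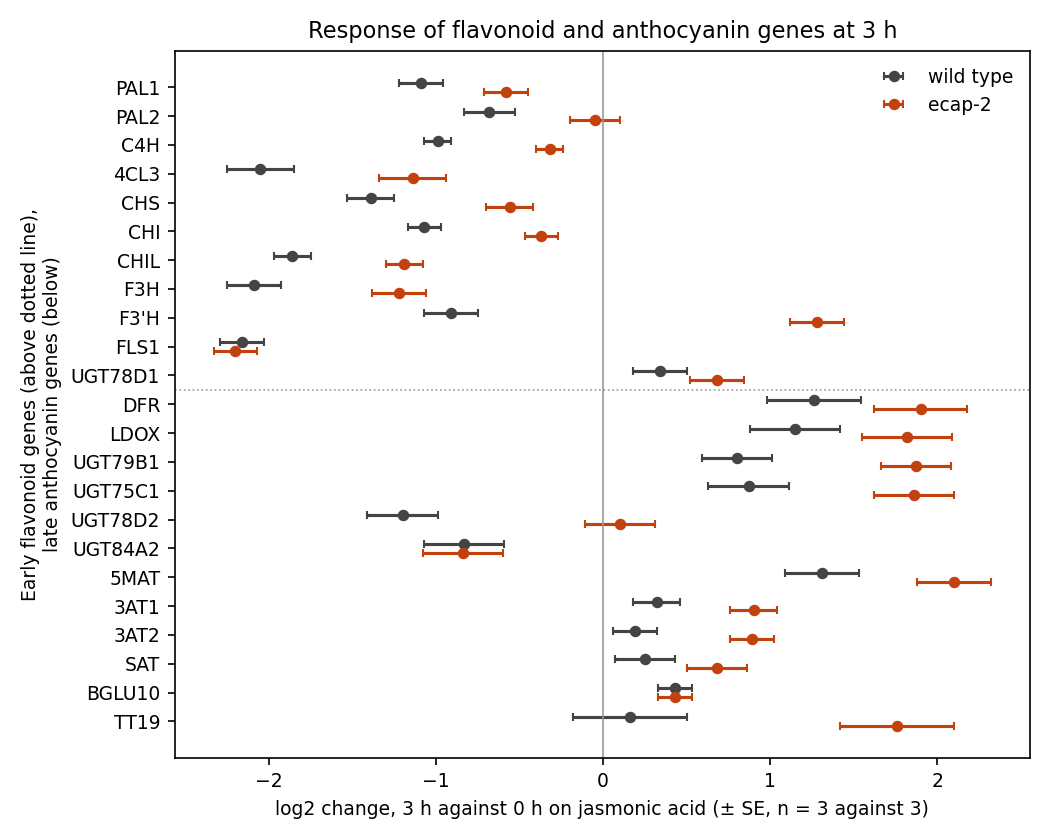
Log2 change from 0 to 3 h on JA (horizontal axis, ± SE, n = 3 libraries per group) of 11 early flavonoid and 12 late anthocyanin genes (vertical axis) in wild type and ecap-2 (points). The median difference between the genotypes' changes is 0.67 for the early and 0.68 for the late genes, and F3'H differs by 2.19.

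Other lists were called for the 3 h difference as well, and none with an estimated correlation (adjusted p = 0.5 to 0.62). Of the root markers, 2 of 12 changed more upward in ecap-2 and 0 more downward (7 and 0 adjusted over the list alone). Their median log2 difference was 0.43 (adjusted p = 0.0018, and adjusted p = 0.5 with an estimated correlation). Of the photosynthesis genes, 0 of 17 changed more upward in ecap-2 and 0 more downward (0 and 0 adjusted over the list alone, and 7 at an unadjusted limma p under 0.05). As a list they had a median log2 difference of 0.23 (adjusted p = 0.00026, and adjusted p = 0.62 with an estimated correlation), a median that turned to -0.01 under quantile normalization. Among indole glucosinolate genes, 1 of 16 changed more upward in ecap-2 and 0 more downward (6 and 1 adjusted over the list alone). The list's median log2 difference was 0.19 (adjusted p = 0.012, and adjusted p = 0.62 with an estimated correlation). Among JA turnover genes, 1 of 9 changed more upward in ecap-2 and 0 more downward (5 and 1 adjusted over the list alone). The members' median log2 difference was 0.39 (adjusted p = 0.012, and adjusted p = 0.62 with an estimated correlation). The turnover call ended without wild type 0 h replicate 3 (adjusted p = 0.052) or ecap-2 0 h replicate 1 (0.08). Among defence genes, 2 of 10 changed more upward in ecap-2 and 0 more downward (2 and 0 adjusted over the list alone). Across the list the median was 0.30 (adjusted p = 0.043, and adjusted p = 0.62 with an estimated correlation). The defence call ended with a pseudocount of 0.1 (adjusted p = 0.44), no filter (0.081) or the block (0.055). It ended without wild type 0 h replicate 1 (0.053), wild type 1 h replicate 1 (0.058) or 2 (0.052), or wild type 3 h replicate 1 (0.08) or 3 (0.078). It also ended without ecap-2 0 h replicate 1 (0.24) or 2 (0.1), or ecap-2 3 h replicate 1 (0.13) or 2 (0.07). After a correction for GC content and length the photosynthesis (adjusted p = 0.54), root (0.052), indole glucosinolate (0.052) and defence (0.052) calls ended. The early flavonoid (1.2e-07), late anthocyanin (0.0001) and JA turnover (0.044) calls held after it.

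At 3 h, 231 of the 432 genes had a more positive and 201 a more negative change in ecap-2, 51 by at least 2-fold. Of the more positive ones, 72 were rises in both genotypes, 64 rises called in ecap-2, 46 falls called in wild type, 22 falls in both and 27 a fall in wild type with a rise in ecap-2. Of the more negative ones, 41 were rises in both, 45 rises called in wild type, 69 falls called in ecap-2, 16 falls in both and 30 a rise in wild type with a fall in ecap-2. The upward 53.5% became 22.1% (172 up and 606 down) under common-total scaling. The count was 658 with a pseudocount of 5, 778 under common-total scaling and 789 with the replicate block. It was 703 with that block and the GC and length correction, and 3604 with weights. It was 1264 without ecap-2 0 h replicate 1 and 869 without ecap-2 3 h replicate 3. It was lower without ecap-2 3 h replicate 2 (134) or 1 (160), ecap-2 0 h replicate 2 (138) or 3 (237), wild type 3 h replicate 1 (190), 2 (222) or 3 (205), or wild type 0 h replicate 2 (202).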

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

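The test of organ share, the correction for GC content and length, and leaving out single libraries for the gene lists were chosen only after the results were seen. Each result in this part stood out because the response to JA differed between ecap-2 and wild type in a test of that difference.

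At 1 h 56 genes differed in response, and 10 of 100 reassignments of genotype within times, the real one included, gave as many (highest other 10317), so chance was not excluded by these splits. All 9 of the others exchanged 2 or 3 more libraries at one time than at the other, a structure that turns the large genotype difference into a difference of responses, and the highest of the remaining 90 gave 32. The lists of JA biosynthesis (median -0.25), salicylic acid (0.26) and seed storage genes (1.18) were called, all lost with an estimated correlation (adjusted p = 0.93, 0.092 and 0.93). The log2 changes on JA of MYB15 (1.76), GA20OX5 (1.70), AAE12 (1.60), RLP6 (1.56) and AT4G15270 (1.33) were more positive in ecap-2, and all 5 calls ended with a pseudocount of 0.1, as did those of GolS3, AT1G76620 and AT5G62360 below. Those of GolS3 (-1.77), LTI78 (-1.48), AT1G54010 (-1.09), AT1G76620 (-1.03) and AT5G62360 (-1.02) were more negative. Without single libraries the count ran from 22 (ecap-2 1 h replicate 2) to 55 (ecap-2 0 h replicate 3).

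At 3 h 432 genes differed in response, and again 10 of 100 reassignments gave as many (highest other 11508), so chance was not excluded by these splits. Of the 9 others, 8 had the unequal structure described for 1 h, and the highest of the remaining 90 gave 2312. Without single libraries the count ran from 134 (ecap-2 3 h replicate 2) to 1264 (ecap-2 0 h replicate 1). Among single genes the differences were 2.19 for F3'H, 1.88 for CYP82C4, 1.68 for BAM5 (-0.448 with a pseudocount of 0.1), 1.65 for AT4G12490 and 1.65 for AT4G12500, near-identical neighbours whose single values are uncertain, and -1.86 for AT1G53690, -1.23 for D27, -1.19 for BGLU18, -1.18 for TPS-CIN and -1.18 for AT1G76620. With a pseudocount of 0.1 the calls of CYP82C4, BAM5, AT4G12490, AT4G12500, TPS-CIN and AT1G76620 ended. BAM5 went from 0.0863 to 6.75 FPKM in wild type and from 4.68 to 129 in ecap-2, and CYP82C4 from 5.16 to 0.413 and from 0.126 to 0.0104, so the size of both and the sign of BAM5 depend on the pseudocount. The lists of JA turnover (0.39), JA-induced defence (0.30), indole glucosinolate (0.19), photosynthesis (0.23, and -0.01 under quantile normalization) and root genes (0.43) had more positive medians in ecap-2, with adjusted p = 0.62, 0.62, 0.62, 0.62 and 0.5 with an estimated correlation.

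The early flavonoid (0.67) and late anthocyanin lists (0.68) were also called for a more positive change in ecap-2 at 3 h (adjusted p = 0.5 each with an estimated correlation), with 5 of 11 and 1 of 12 genes past the threshold. For early genes such as C4H and CHI, part of this difference is a lower level in ecap-2 at 0 h. A trend with GC content or length as the whole cause is argued against by the correction, after which the median over the 23 genes was 0.926 of its value before (0.62 against 0.67) and both lists stayed called. A changed share of root and shoot tissue stays open, since over the libraries the mean of the 23 genes exceeded that of the photosynthesis list by 0.49 ± 0.26 and that of the root list by 0.31 ± 0.20 (SE), which is 1.85 and 1.59 times the SE, under the bound of 2.18 set by the t distribution. The lower ECAP transcript, a changed stage or condition of the ecap-2 seedlings, and a separate batch of the mutant remain open as well, and the design cannot separate them.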

How the results depend on the processing

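The GC and length correction, alone or with the block, nuclear genes only and leaving out libraries for lists were chosen after seeing the data. Among counts and similarity values, 318 stayed close to those reported and 54 moved. Of named gene results 17179 kept their side of the threshold, 494 fell short, 85 newly passed and 12 calls reversed. Among lists 5568 kept it, 124 fell short and 83 newly passed. The cause was not tested unless stated. At 1 h, 32 genes responded differently with pseudocount 0.1, 114 with 5, 213 with library weights and 15 with only the libraries compared. At 3 h, 658 did with pseudocount 5, 778 under common-total scaling and 3604 with weights.

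With a change of at least 2-fold, a stricter criterion by construction, 1073, 1204 and 528 genes passed in wild type (1 h, 3 h, 3 h against 1 h), 1048 and 1303 in ecap-2 (1 h, 3 h), 629, 569, 1136 and 653 between genotypes (0 h, 1 h, 3 h, average), and 19 and 51 for the differences of response. Gene list calls numbered 25 with an estimated correlation and 106 by fry. The correlation of responses at 1 h was 0.865 with a pseudocount of 0.1, 0.916 with 5 and 0.884 without a filter.

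These directions reversed. With a pseudocount of 0.1 the difference of response of BAM5 at 3 h was -0.448. After rescaling to a common total TIP41 at 3 h was -0.001 between genotypes, and averaged over times TPL was -0.017, TPR1 -0.043, PP2AA3 -0.047, ACT2 -0.051 and TIP41 -0.052. Under quantile normalization RCA at 3 h was -0.047, and averaged LHCB1.3 -0.144 and ACT2 -0.064. After the GC and length correction the averages of LHCB1.3 and TIP41 were -0.02 and -0.011.

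Leaving out single libraries gave 22 to 55 genes for the difference at 1 h and 134 to 1264 at 3 h, correlations of 0.881 to 0.899 at 1 h and 0.842 to 0.877 at 3 h, and slopes of 0.872 to 0.929 and 0.868 to 0.911. Replicate numbers are not stated to pair the libraries: the 45 same-number pairs of residuals correlated with r from -0.157 to 0.322, 19 of them above 0.1, though 13 of 18 libraries were closest to their own number, a hint from the data. With the number as a block 789 genes differed in response at 3 h, and with the GC and length correction as well 107 at 1 h and 703 at 3 h. Alternatives planned for tables of counts were not run because the values are FPKM. Depth is unknown, so precision at low FPKM cannot be given.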

Other observations

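All gene groups in the next 2 paragraphs, and the tests of library scaling, of a separate batch, of time of day and of GC content, were chosen after results were seen, while the counts over other splits were planned.

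Genes of the iron deficiency response fell on JA plates. In wild type 1 of 13 rose and 10 fell (1 and 10 adjusted over the list alone) at 1 h and 2 of 13 rose and 10 fell (2 and 10 adjusted over the list alone) at 3 h. In ecap-2 1 of 13 rose and 8 fell (1 and 9 adjusted over the list alone) at 1 h and 1 of 13 rose and 10 fell (1 and 10 adjusted over the list alone) at 3 h. The medians were -1.51, -1.69, -1.16 and -1.18 in that order. BHLH38, a transcription factor gene induced without iron, fell from 40.9 ± 17 to 6.11 ± 1.2 FPKM (log2 change -2.49 ± 0.39, adjusted p = 0.00018) in wild type at 1 h. F6'H1, which makes coumarins that mobilise iron, rose from 8.8 ± 0.095 to 50.9 ± 6.9 FPKM (log2 change 2.40 ± 0.15, adjusted p = 1.3e-09) at 3 h. Among heat shock genes in wild type 0 of 7 rose and 3 fell (0 and 3 adjusted over the list alone) at 1 h and 1 of 7 rose and 5 fell (1 and 5 adjusted over the list alone) at 3 h. In ecap-2 1 of 7 rose and 2 fell (2 and 2 adjusted over the list alone) and 0 of 7 rose and 3 fell (0 and 3 adjusted over the list alone) at these times, and the medians were -0.46, -1.33, 0.18 and -0.08. HSP101 fell from 15 ± 0.79 to 3.73 ± 0.3 FPKM (log2 change -1.76 ± 0.14, adjusted p = 1.9e-08) in wild type at 3 h.

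All 7 tested genes of the EARLI1 cluster, neighbouring lipid transfer protein genes on chromosome 4, were higher in ecap-2 at each time (7 adjusted over the list alone), with medians of 1.57 at 0 h, 1.23 at 1 h and 3.04 at 3 h. EARLI1 rose from 52.2 ± 5.6 to 457 ± 64 FPKM (log2 difference 3.10 ± 0.15, adjusted p = 6.1e-10) at 3 h. The sequences are near-identical, so single members are uncertain and not independent of each other. Of the plastid-encoded genes 1 of 28 were higher and 6 lower (1 and 4 adjusted over the list alone) in ecap-2 at 0 h, 0 of 28 were higher and 18 lower (0 and 20 adjusted over the list alone) at 1 h and 1 of 28 were higher and 9 lower (1 and 6 adjusted over the list alone) at 3 h. These 4 groups were built around genes that already stood out in these libraries, so their counts are not independent evidence and no list p-value is given.

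First weighed are the 12257 genes that differed between genotypes averaged over times. Of 100 genotype reassignments within times, 1, the real one, gave as many (highest other 5886), which argues against chance for these libraries. A trend with GC content or length as the whole cause is argued against by a corrected count of 0.982 of that before. Library scaling as the whole cause is argued against because no common factor on the ecap-2 libraries, from -0.50 to 0.50 on the log2 scale, brought the count under 0.999 of that on deposited values (12246, with 5180 higher and 7066 lower). A separate growth or library batch of each genotype cannot be told apart from genotype: 2 of the first 6 principal components separate the genotypes at every time, and no label gives a batch.

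Time of day is a candidate explanation for part of the change between 0 and 3 h. All 10 of 10 gene and genotype cases (CCA1, LHY, PRR7, PRR5 and GI) went the way the hours after dawn would give, CCA1 by -2.41 in wild type and -2.53 in ecap-2 and GI by 1.07 and 1.04. An effect of JA or of transfer on the clock genes was not separated from it, since no mock-treated seedlings were used here.

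For comparisons of 3 libraries against 3, 10 splits are too few for a share under 0.05, and in each 1 split, the real one, gave as many genes as observed. The real and highest other counts were 6050 and 4 (wild type 1 h), 7400 and 0 (3 h), 5164 and 1 (3 h against 1 h), 5984 and 1 (ecap-2 1 h), 8065 and 44 (3 h), 7880 and 14 (between genotypes at 0 h), 7113 and 0 (1 h) and 10252 and 1 (3 h).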
